A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

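RNA from 12 cultures of Saccharomyces cerevisiae was measured on Affymetrix yeast arrays. Per the labels, there were 4 strains, named WT, WT(hsf1), hac1∆ and hac1∆(hsf1), each grown as 3 biological replicates. Cells in early exponential phase in medium lacking uracil received 2.5 mM dithiothreitol (DTT), a reducing agent that disturbs disulfide bond formation in the endoplasmic reticulum (ER), for 2 h before RNA extraction with a column kit, amplification with a 3' in vitro transcription kit and biotin labelling. No culture without DTT was among the samples, so the effect of DTT itself was not analysed here. The labels do not say what the addition "(hsf1)" stands for, a mutation, a plasmid or something else, and it is used here only as a strain name. Whether it is the same change in WT(hsf1) and in hac1∆(hsf1) is not stated either.

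The values deposited by the authors are log2 signals, 1 per probe set and array. The submitters' processing notes name PLIER as the tool, with no version. The background correction, the normalization between arrays, the offset and the base of the logarithm are not given in the sources used here. That the deposited unit is log2 was read from the values, which ran from 4.84 to 12.75 over 10928 probe sets, with array medians between 5.9952 and 6.0654. The lower end acts as a floor, so fold changes of dim genes are compressed toward 0. The log2 values were used as deposited, with no further normalization and no pseudocount.

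Probe sets were matched to genes through the platform's annotation and the yeast gene table of the reference. A gene symbol was listed for 7244 probe sets, several symbols for 1, and none for 3683, control probe sets included. Of all probe sets, 5498 were annotated to S. cerevisiae, 3517 had no listed gene and 166 were controls. The other 1747 had a listed gene that was not found in the S. cerevisiae gene table. They were taken as probe sets of another yeast, Schizosaccharomyces pombe, which shares the array, with no check of the species. For 47 genes with more than 1 probe set the one with the highest mean was used, and 12 symbols were updated through the gene table, which left 5449 genes. Background was set at 5.49, the 95th percentile of the mean signal of the 1747 probe sets taken as S. pombe. Of the genes tested, 5236 had a mean above it and 213 did not. No gene was removed for low signal. No 2 arrays held the same values. The number of arrays limits the precision.

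A linear model with 1 mean per strain was fitted to all 12 arrays in limma 3.58.1 (R 4.3.3), which left 8 residual degrees of freedom, and 6 comparisons were drawn from it. These were hac1∆ minus WT, WT(hsf1) minus WT, hac1∆(hsf1) minus hac1∆, hac1∆(hsf1) minus WT(hsf1), hac1∆(hsf1) minus WT, and the interaction, which is the hsf1 effect in hac1∆ cells minus the hsf1 effect in WT cells. Moderated statistics from limma's empirical Bayes step were adjusted by the Benjamini-Hochberg method over all genes of a comparison. A gene with an adjusted p under 0.05 is called higher or lower. Changes are log2 fold changes with their standard error (SE), from 3 arrays per strain, unless a level is given with its standard deviation (SD). The SE rests on a variance per gene pooled over all 12 arrays, so it is equal for every pair of strains. It does not measure the spread of the compared strains alone, and for HSF1 it holds the spread of the WT arrays in every comparison.

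For gene groups, 22 lists were tested with limma's camera, which asks whether the members moved relative to all other genes. The lists were ER protein folding, ER-associated degradation, ER translocation, protein glycosylation, ER-Golgi vesicle transport, phospholipid synthesis, cytosolic chaperones, mitochondrial chaperones, general stress genes, the proteasome, oxidative stress genes, sulfur assimilation, amino acid synthesis, ribosomal proteins, ribosome biogenesis, ergosterol synthesis, respiration and the TCA cycle, glycolysis and fermentation, the iron regulon, the cell wall, mating type and ploidy markers, and auxotrophic marker genes. Camera used its preset correlation of 0.01 between genes, and its p-values were adjusted over the 132 pairs of a list and a comparison. Of these, 72 passed. With a correlation estimated from the residuals camera passed 0, with 14 at an unadjusted p under 0.05, and the smallest adjusted p was 0.282. That adjusted p is given beside each list. The rotation test fry, which asks only whether a list's own genes moved on balance one way, passed 113 of the 132. Members were also counted with p-values adjusted over the list alone.

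Genes to be named were fixed by a rule. In every comparison they were HAC1, HSF1, IRE1, KAR2, PDI1, ERO1, SSA1, SSA4, HSP82, HSP104, HSP12 and URA3. To these were added the 8 genes with the largest increase and the 8 with the largest decrease among called genes whose replicates did not overlap and whose mean was above background in at least 1 of the strains (for the interaction, with no overlap rule), and up to 4 called members with the largest moderated statistic of each list that passed. The comparisons, tests, gene lists, this rule and the alternatives were chosen before the data were examined, except where the text says otherwise.

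The fit was first tested on simulated data with known changes. Results were recomputed under 12 alternatives, among them quantile normalization, median centring, only genes above background, the mean of a gene's probe sets, no cross-hybridising probe sets (116 of those tested), array weights, an intensity trend with robust variances, only the arrays of the strains compared, the replicate number as a block in all strains or in the hac1∆ strains alone, a 2-fold minimum and an estimated correlation, and with each of the 12 arrays left out. The block in the hac1∆ strains was added after the data were seen, because hac1∆ and hac1∆(hsf1) arrays with equal numbers deviated together from their strain means (residual correlations of 0.50, 0.15 and 0.34 in replicates 1 to 3), which the labels do not explain. WT replicate 2 stood apart from the other WT arrays, and its omission was looked at in more detail after the values were seen. Figures and further tests used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.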

Results

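Signals of 5449 yeast genes were compared in 12 DTT-treated cultures, with 3 replicates of each strain. The strains were WT and hac1∆, each without and with the addition that its name gives as (hsf1). The number of arrays limits the precision of what follows. Correlations across genes between replicate arrays, which describe the arrays and do not treat genes as independent replicates, were 0.997 to 0.998 in WT(hsf1), 0.997 to 0.999 in hac1∆ and 0.992 to 0.994 in hac1∆(hsf1). In WT they were 0.988 to 0.996, with WT replicate 2 apart from the other two. That array correlated at 0.973 to 0.978 with the hac1∆(hsf1) arrays, where WT replicate 1 reached 0.942 to 0.951 and WT replicate 3 reached 0.939 to 0.948. Values without WT replicate 2 are given wherever they change a call or move a called value by more than 1.5 times. Replicate 2 of hac1∆(hsf1) had the lowest mean ribosomal RNA signal, 8.30 against 8.95 to 9.97 on the other arrays.

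**Figure D1:**
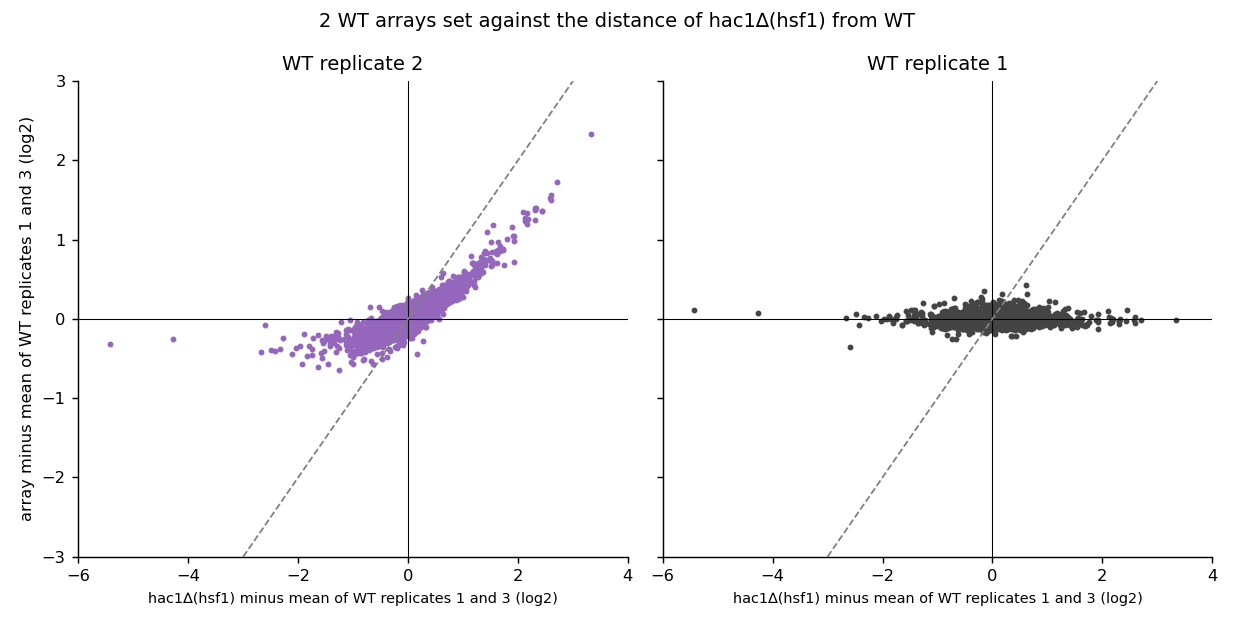
Each gene's log2 signal on WT replicate 2 (left, vertical axis) or WT replicate 1 (right, vertical axis) minus the mean of WT replicates 1 and 3, against hac1∆(hsf1) minus that mean (horizontal axis), in log2 units. WT replicate 1 is itself part of that mean, which narrows the right panel by construction. The dashed line marks equal values, and on the left 195 of 195 genes at least 2-fold apart between hac1∆(hsf1) and the other WT arrays lie between the levels of those strains.

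HAC1 (YFL031W), which encodes the transcription factor of the unfolded protein response, was below background in both hac1∆ strains. Its log2 signal was 10.58 ± 0.22 (SD, n = 3) in WT and 10.80 ± 0.08 in WT(hsf1). It was 5.24 ± 0.004 in hac1∆ and 5.26 ± 0.05 in hac1∆(hsf1), below the background of 5.49 on all 6 arrays without HAC1. Set against that background, HAC1 was at least 34-fold lower in hac1∆ than in WT and at least 39.6-fold lower in hac1∆(hsf1) than in WT(hsf1). HSF1 (YGL073W), which encodes the heat shock transcription factor, stood at 10.67 ± 0.14 in hac1∆(hsf1), 8.52 ± 0.11 in WT(hsf1) and 7.83 ± 0.07 in hac1∆. In WT it was 8.08 and 8.11 in replicates 1 and 3 and 9.61 in replicate 2. URA3 (YEL021W), which encodes a uracil synthesis enzyme and is a common selection marker, was 11.79 ± 0.14 in WT, 10.91 ± 0.02 in WT(hsf1), 12.13 ± 0.06 in hac1∆ and 9.60 ± 0.08 in hac1∆(hsf1).

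**Figure D2:**
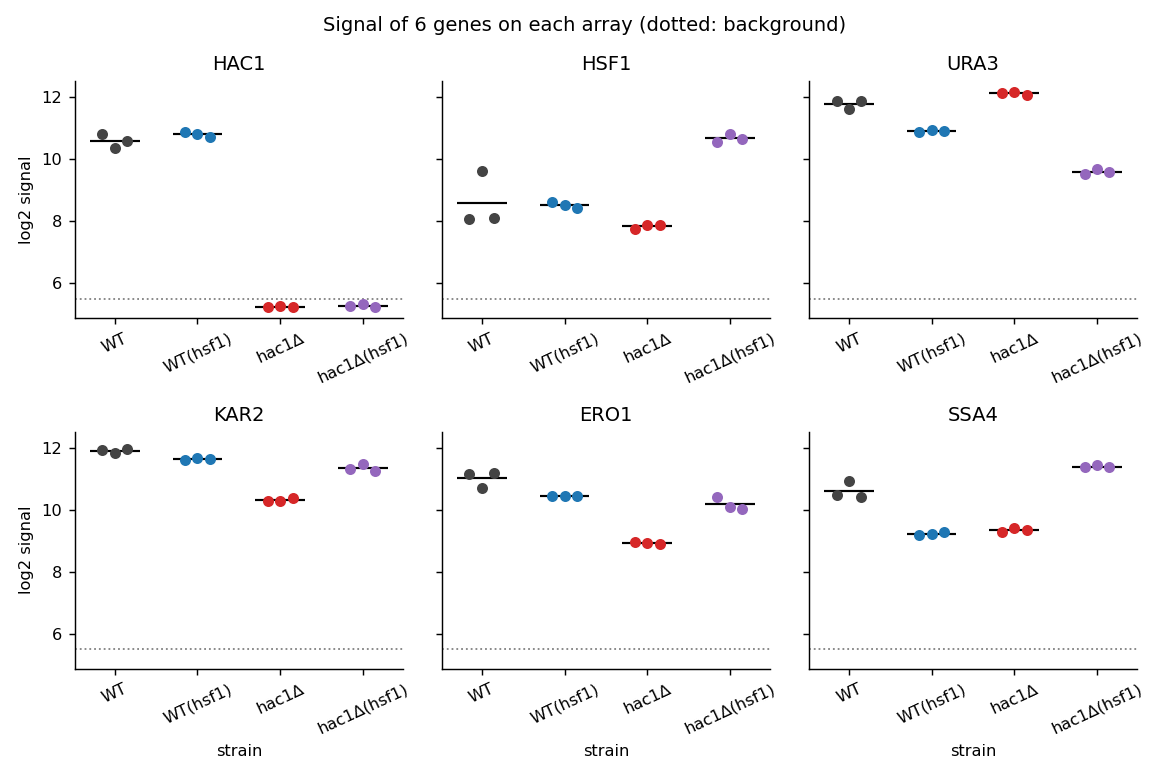
Log2 signal (vertical axis) of 6 genes on each of the 12 arrays, by strain (horizontal axis). Points are single arrays, short lines are means of 3 arrays and the dotted line is the background of 5.49, and HSF1 on WT replicate 2, at 9.61, stands above 8.08 and 8.11 on the other WT arrays.

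The comparison of hac1∆ with WT asks what the loss of HAC1 changed in DTT-treated cells. Genes that fold proteins in the ER fell. KAR2, the Hsp70 chaperone of the ER lumen, fell 3.02-fold (log2 fold change −1.60 ± 0.06, limma adjusted p = 5.75e-09), and ERO1, the ER thiol oxidase, fell 4.23-fold (−2.08 ± 0.12, adjusted p = 8.43e-08). SIL1, a nucleotide exchange factor for Kar2, fell 5.22-fold (−2.39 ± 0.09, adjusted p = 5.75e-09). PDI1, the main protein disulfide isomerase, fell less, at −0.28 ± 0.06 (adjusted p = 0.00199), and its relative MPD1 changed by −2.15 ± 0.09. Among the 17 ER folding genes measured, 14 fell and 1 rose, and their median change was −0.98 (camera adjusted p = 9.23e-09, adjusted p = 0.282 with an estimated correlation).

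Lists of other steps of the secretory pathway also shifted down from WT to hac1∆ at camera's preset correlation, though many of their members did not fall. Of 13 genes of translocation into the ER, 9 fell and 1 rose (median −0.42, camera adjusted p = 0.000183, adjusted p = 0.307 with an estimated correlation). SEC62 changed by −1.02 ± 0.06 and SEC61, the channel subunit, by −0.50 ± 0.06. Of 28 genes of vesicle transport between the ER and the Golgi, 17 fell and 2 rose (median −0.30, camera adjusted p = 4.12e-05, adjusted p = 0.282 with an estimated correlation). ERV29, a cargo receptor, changed by −0.93 ± 0.06. In ER-associated degradation 8 of 16 genes fell and 2 rose (median −0.12, camera adjusted p = 0.027, adjusted p = 0.319 with an estimated correlation). DER1 changed by −1.50 ± 0.08 and the ubiquitin ligase gene HRD1 by −0.44 ± 0.04. Protein glycosylation genes moved both ways, 11 of 23 down and 5 up (median −0.07, camera adjusted p = 0.0257, adjusted p = 0.498 with an estimated correlation). PMT3, a protein mannosyltransferase, changed by −1.18 ± 0.09. The list median was −0.14 without WT replicate 2, −0.04 without WT replicate 3 and −0.13 without hac1∆ replicate 1, and without WT replicate 1 it was −0.06 and the list no longer passed. Phospholipid synthesis genes fell in 10 of 15 cases and rose in 1 (median −0.23, camera adjusted p = 0.00395, adjusted p = 0.282 with an estimated correlation). INO1, which makes inositol phosphate, changed by −0.31 ± 0.05.

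Cytosolic chaperones and general stress genes were also lower in hac1∆ than in WT. SSA4, a stress-inducible Hsp70, fell 2.41-fold (−1.27 ± 0.10, limma adjusted p = 1.22e-06) and SSA3 changed by −1.52 ± 0.20, while HSP104, a disaggregase, changed by −0.35 ± 0.06 and HSP82, an Hsp90, by −0.18 ± 0.04. SSA4 and SSA3 are among the genes for which WT replicate 2 lay above the other WT arrays, and without it they changed by −1.11 and −1.19. Of 21 cytosolic chaperone genes 14 fell and the rest were not called (median −0.22, camera adjusted p = 0.000205, adjusted p = 0.327 with an estimated correlation). Of 18 general stress genes 12 fell and 1 rose (median −0.34, camera adjusted p = 9.62e-06, adjusted p = 0.303 with an estimated correlation). CTT1, catalase T, changed by −1.75 ± 0.12 and HSP12 by −0.35 ± 0.05. HSF1 changed by −0.77 ± 0.30 (adjusted p = 0.0464) and by −0.26 without WT replicate 2. Its call ended on leaving out any 1 array of WT(hsf1), hac1∆ or hac1∆(hsf1), at −0.79 to −0.73, with an intensity trend, and in a fit of the compared strains alone. SSA1 changed by −0.20 ± 0.06 (adjusted p = 0.0187), and its call ended without hac1∆ replicate 1 or 3, at −0.18 and −0.17, and with quantile normalization, at −0.09.

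Higher in hac1∆ than in WT were the lists of the cell wall, ribosomal proteins, the proteasome, ergosterol synthesis and sulfur assimilation. Cell wall genes rose in 14 of 20 cases and the rest were not called (median 0.37, camera adjusted p = 1.49e-05, adjusted p = 0.282 with an estimated correlation). YPS3, a yapsin protease, rose 2.3-fold and FKS1, a glucan synthase subunit, rose by 0.64 ± 0.06. Ribosomal protein genes rose in 88 of 127 cases and fell in 1 (median 0.28, camera adjusted p = 1.79e-11, adjusted p = 0.476 with an estimated correlation). Proteasome genes rose in 22 of 33 cases and the rest were not called (median 0.19, camera adjusted p = 0.000494, adjusted p = 0.498 with an estimated correlation). Ergosterol synthesis genes rose in 16 of 23 cases and fell in 2 (median 0.27, camera adjusted p = 0.000152, adjusted p = 0.282 with an estimated correlation). ERG6, a sterol methyltransferase, rose by 0.71 ± 0.06. Sulfur assimilation genes rose in 13 of 20 cases and fell in 1 (median 0.38, camera adjusted p = 0.00683, adjusted p = 0.595 with an estimated correlation). Their median was 0.24 without hac1∆ replicate 2, and MET1, an enzyme of siroheme synthesis, changed by 1.27 ± 0.13. Ribosome biogenesis did not pass (camera adjusted p = 0.0967, median 0.10) but did without WT replicate 3 or hac1∆ replicate 2, at 0.12 and 0.11. IRE1, which encodes the ER stress sensor, changed by 0.18 ± 0.05 (adjusted p = 0.00778) and URA3 by 0.34 ± 0.07 (adjusted p = 0.00116).

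Over all genes 1550 were higher and 1214 lower in hac1∆ than in WT (limma), of which 12 and 89 by at least 2-fold. Under the naming rule the largest increases were in MET1, YPS3, NCA3 (1.84), ADH6, an alcohol dehydrogenase (1.54), the pheromone-regulated membrane protein genes PRM10 (1.46) and PRM5 (1.34), AFB1 (1.32) and PGU1, a pectin-degrading enzyme (1.13). The largest decreases were in HAC1, SIL1, ULI1 (−4.29), a gene induced by the unfolded protein response, YOR387C (−4.04), MF(ALPHA)1, the precursor of alpha-factor (−2.33), CYC7, a cytochrome c (−2.29), MCD4, an enzyme of GPI anchor synthesis (−2.27), and SHH3 (−2.24). Without WT replicate 2 the numbers at least 2-fold apart were 20 higher and 98 lower. The arrays of the strains did not overlap for 3275 genes, and chance gives 10% of genes. Adjusted over the list alone, the counts of each passing list were equal to those over all genes except for the genes higher among cytosolic chaperones (1), ergosterol synthesis (17), the proteasome (23), glycosylation (6) and sulfur assimilation (14). Among the other lists, amino acid synthesis had a median of 0.13, a mean of −0.12 and an upward test that did not pass (camera adjusted p = 0.779), with 16 members higher and 10 lower.

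WT(hsf1) was set against WT to see what the addition named hsf1 changed in cells that have HAC1. By camera at its preset correlation, the lists of ribosomal proteins, ribosome biogenesis and the iron regulon were higher in WT(hsf1). Those of general and oxidative stress, respiration and sulfur assimilation were lower, and no list passed with an estimated correlation. Ribosomal protein genes rose in 125 of 127 cases and the rest were not called (median 1.19, camera adjusted p = 1.52e-35, adjusted p = 0.282 with an estimated correlation). RPS9A changed by 2.36 ± 0.09 (limma adjusted p = 4.48e-10), RPL22B by 2.17 ± 0.08 and RPS22B by 2.09 ± 0.09. All 45 ribosome biogenesis genes rose (median 0.77, camera adjusted p = 1.83e-14, adjusted p = 0.282 with an estimated correlation). NOP1, the fibrillarin of the nucleolus, changed by 1.56 ± 0.05, and NSR1, also nucleolar, by 1.58 ± 0.08. Iron regulon genes rose in 13 of 19 cases and fell in 1 (median 0.57, camera adjusted p = 0.000617, adjusted p = 0.327 with an estimated correlation). FIT3, a cell wall protein that retains siderophores, rose 5.77-fold (2.53 ± 0.09, adjusted p = 4.16e-10). SIT1, a siderophore transporter, rose by 2.30 ± 0.06, FET3, a ferroxidase, by 2.24 ± 0.09 and FIT2 by 2.18 ± 0.09. Without WT replicate 2 the medians were 1.12 for ribosomal proteins, 0.73 for ribosome biogenesis and 0.70 for the iron regulon, and these lists still passed.

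General stress genes fell in all 18 cases in WT(hsf1) (median −1.11, camera adjusted p = 6.03e-10, adjusted p = 0.282 with an estimated correlation). CTT1 fell 9.24-fold (−3.21 ± 0.12, limma adjusted p = 4.59e-10), GAD1, glutamate decarboxylase, changed by −1.93 ± 0.07 and HSP12 by −0.89 ± 0.05. Sulfur assimilation genes fell in 19 of 20 cases and the other was not called (median −1.81, camera adjusted p = 6.83e-09, adjusted p = 0.327 with an estimated correlation). SUL1, a sulfate permease, changed by −2.98 ± 0.14 and MET3, ATP sulfurylase, by −2.87 ± 0.16. Genes of respiration and the TCA cycle fell in 37 of 42 cases and the rest were not called (median −0.96, camera adjusted p = 3.06e-14, adjusted p = 0.282 with an estimated correlation). SDH2, a succinate dehydrogenase subunit, changed by −1.62 ± 0.07. Oxidative stress genes fell in 22 of 28 cases and rose in 2 (median −0.58, camera adjusted p = 6.58e-06, adjusted p = 0.282 with an estimated correlation). TSA2, a peroxiredoxin, changed by −2.05 ± 0.07. Proteasome genes fell in 26 of 33 cases and the rest were not called (median −0.23, camera adjusted p = 0.000154, adjusted p = 0.465 with an estimated correlation). The medians without WT replicate 2 were −1.05 for general stress, −1.83 for sulfur assimilation, −0.99 for respiration and −0.55 for oxidative stress, and these lists still passed. The largest decreases under the naming rule were in SIP18 (−4.25) and GRE1 (−4.14), both hydrophilic proteins of the desiccation response, followed by CTT1, PDC6, a minor pyruvate decarboxylase (−3.15), SHH3 (−3.01), SUL1, MET3 and TKL2, a transketolase (−2.83).

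Cytosolic chaperones, many of them known targets of Hsf1, were lower in WT(hsf1) than in WT. Of 21 genes 17 fell and 1 rose (median −0.50, camera adjusted p = 2.96e-05, adjusted p = 0.292 with an estimated correlation). SSA4 changed by −1.38 ± 0.10 (limma adjusted p = 9.76e-08), HSP104 by −0.70 ± 0.06, HSP82 by −0.57 ± 0.04 and SSA1 by −0.43 ± 0.06. HSF1 itself was not called, at −0.08 ± 0.30 (adjusted p = 0.831), and without WT replicate 2 it was called at 0.43, with the opposite sign. In ER-associated degradation 12 of 16 genes fell and 1 rose (median −0.30, camera adjusted p = 0.0095, adjusted p = 0.282 with an estimated correlation). Among ER folding genes 9 of 17 fell and 2 rose, and the list did not pass (median −0.22, camera adjusted p = 0.128). Without WT replicate 2 it did, with 12 lower and a median of −0.32. ERO1 changed by −0.57 ± 0.12 (adjusted p = 0.000986) and KAR2 by −0.27 ± 0.06 (adjusted p = 0.0021). With quantile normalization KAR2 was not called, at −0.08. Glycosylation genes rose in 11 of 23 cases and fell in 2 (median 0.16, camera adjusted p = 0.0335, adjusted p = 0.502 with an estimated correlation). Without WT replicate 2 the median was 0.10 and the list did not pass. URA3 changed by −0.88 ± 0.07 (adjusted p = 1.23e-07).

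Small changes in 3 further genes depended on single arrays. HAC1 changed by 0.22 ± 0.09 (limma adjusted p = 0.0385) and by 0.33 without WT replicate 1. Its call ended without WT replicate 2, at 0.11, and without WT replicate 3, WT(hsf1) replicate 1 or 2, or hac1∆ replicate 1 or 2, at 0.19 to 0.22. It also ended with array weights, with quantile normalization and in a fit of the compared strains alone, at 0.11 to 0.22. IRE1 changed by 0.13 ± 0.05 (adjusted p = 0.0275), and its call ended without WT replicate 1 or 2 or any array of WT(hsf1), at 0.11 to 0.14. PDI1 changed by −0.17 ± 0.06 (adjusted p = 0.0253), and its call ended without WT replicate 1 or 3 or WT(hsf1) replicate 1 or 3, at −0.16 to −0.12, and with quantile normalization, at −0.08.

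In all, 1760 genes were higher and 1840 lower in WT(hsf1) than in WT (limma), of which 195 and 215 by at least 2-fold. The arrays did not overlap for 3896 genes, and chance gives 10%. The largest increases under the naming rule were in the 4 iron genes and 3 ribosomal protein genes given above and in DIP5, an amino acid permease (2.19). Adjusted over the list alone, the counts of each passing list were equal to those over all genes except for the iron regulon, with 14 higher. Ergosterol synthesis did not pass (camera adjusted p = 0.0712, median 0.20) but did without WT replicate 1, at a median of 0.25. Mating type and ploidy markers, examined as a check of cell type, had a median of −0.04, a mean of −0.08 and an upward test that did not pass (camera adjusted p = 0.995), with 5 higher and 5 lower of 16. The list mixes genes expressed in a cells with genes expressed in alpha cells, so a directional test over it cannot decide on cell type.

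The addition of the same name was then examined in cells without HAC1, by comparing hac1∆(hsf1) with hac1∆. HSF1 rose 7.18-fold (2.84 ± 0.30, limma adjusted p = 5.63e-06), and cytosolic chaperones rose too. SSA3, an inducible Hsp70, rose 7.08-fold (2.82 ± 0.20, adjusted p = 2.45e-07) and SSA4 rose 4.14-fold (2.05 ± 0.10, adjusted p = 4.08e-08), while HSP104 (0.32 ± 0.06), HSP82 (0.28 ± 0.04) and SSA1 (0.24 ± 0.06) rose less. Of 21 cytosolic chaperone genes 19 rose and 1 fell (median 0.38, camera adjusted p = 1.63e-07, adjusted p = 0.282 with an estimated correlation). Mitochondrial chaperones rose in 6 of 7 cases and fell in 1 (median 0.34, camera adjusted p = 0.00851, adjusted p = 0.282 with an estimated correlation). HSP60, the chaperonin of the mitochondrial matrix, changed by 0.50 ± 0.06.

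The ER folding genes did not move together between these strains. KAR2 rose 2.06-fold (1.04 ± 0.06, limma adjusted p = 1.06e-07) and ERO1 2.36-fold (1.24 ± 0.12, adjusted p = 3.06e-06), whereas PDI1 fell (−0.21 ± 0.06, adjusted p = 0.0092). Over the 17 genes of the list 3 rose, 4 fell and 10 were not called. The list did not pass, with a median of −0.02, a mean of 0.07 and an upward test (camera adjusted p = 0.76). Translocation genes fell in 9 of 13 cases and the rest were not called (median −0.27, camera adjusted p = 0.00843, adjusted p = 0.436 with an estimated correlation). SEC66, a subunit of the Sec63 complex, changed by −0.71 ± 0.08, and without hac1∆(hsf1) replicate 3 the list median was −0.17. Glycosylation genes fell in 17 of 23 cases and rose in 2 (median −0.28, camera adjusted p = 0.00338, adjusted p = 0.39 with an estimated correlation). IRE1 changed by −0.16 ± 0.05 (adjusted p = 0.0138), a call that ended without hac1∆ replicate 3 or hac1∆(hsf1) replicate 3, at −0.13 each.

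General stress genes rose in 15 of 18 cases in hac1∆(hsf1) and the rest were not called (median 0.50, camera adjusted p = 1.85e-06, adjusted p = 0.282 with an estimated correlation). GPH1, glycogen phosphorylase, changed by 1.26 ± 0.10 and HSP12 by 0.36 ± 0.05 (limma adjusted p = 7.79e-05). Iron regulon genes rose in 10 of 19 cases and fell in 2 (median 0.30, camera adjusted p = 0.0074, adjusted p = 0.416 with an estimated correlation). Ribosomal protein genes fell in 125 of 127 cases and the rest were not called (median −0.84, camera adjusted p = 4.5e-35, adjusted p = 0.282 with an estimated correlation). RPL5 changed by −1.27 ± 0.07. Ribosome biogenesis genes fell in 40 of 45 cases and rose in 2 (median −0.40, camera adjusted p = 4.52e-08, adjusted p = 0.341 with an estimated correlation). NOP56 changed by −1.17 ± 0.11. Ergosterol synthesis genes fell in 21 of 23 cases and rose in 2 (median −0.53, camera adjusted p = 1.21e-07, adjusted p = 0.282 with an estimated correlation). HMG1, an HMG-CoA reductase, changed by −0.85 ± 0.07. Genes of respiration fell in 25 of 42 cases and the rest were not called (median −0.22, camera adjusted p = 0.000151, adjusted p = 0.341 with an estimated correlation). Sulfur assimilation genes fell in 14 of 20 cases and rose in 1 (median −0.42, camera adjusted p = 0.00289, adjusted p = 0.578 with an estimated correlation). Genes of glycolysis and fermentation fell in 8 of 18 cases and the rest were not called (median −0.13, camera adjusted p = 0.0195, adjusted p = 0.403 with an estimated correlation).

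URA3 had the largest decrease under the naming rule from hac1∆ to hac1∆(hsf1), 5.77-fold (−2.53 ± 0.07, limma adjusted p = 2.22e-10). Other genes of uracil synthesis and uptake were among the 8 largest decreases, namely URA1, dihydroorotate dehydrogenase (−1.70), URA2, which starts the pathway (−1.41), and FUI1, the uridine permease (−1.33). The rest were MAL32, a maltase (−1.83), CYB5, cytochrome b5 (−1.44), YHB1, a nitric oxide oxidoreductase (−1.39) and ELO2, a fatty acid elongase (−1.30). The largest increases were in HSF1, SSA3, YOR338W (3.46), YIL089W (2.73), YNL194C (2.73), SUC2, invertase (2.71), YNL195C (2.68) and SIP4, an activator of gluconeogenic genes (2.61). There were 1442 genes higher and 1673 lower (limma), of which 141 and 50 by at least 2-fold. The arrays did not overlap for 3421 genes, against 10% by chance. Adjusted over the list alone, counts of passing lists were equal to those over all genes except for translocation, with 10 lower, and the iron regulon, with 11 higher. Amino acid synthesis, which did not pass, had a median of −0.17, a mean of 0.01 and a downward test (camera adjusted p = 0.35).

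hac1∆(hsf1) was compared with WT(hsf1) for the effect of losing HAC1 in the strains with the addition. At camera's preset correlation, the lists of cytosolic chaperones, general and oxidative stress, sulfur assimilation, respiration and the proteasome were higher in hac1∆(hsf1). Those of ribosomal proteins, ribosome biogenesis, ergosterol synthesis, ER folding, translocation, glycosylation and ER-Golgi transport were lower, and no list passed with an estimated correlation. HSF1 rose 4.45-fold (2.15 ± 0.30, limma adjusted p = 2.12e-05), SSA4 rose 4.48-fold (2.16 ± 0.10, adjusted p = 1.04e-09) and HSP82 rose by 0.67 ± 0.04. In the list 19 of 21 cytosolic chaperone genes rose and 1 fell (median 0.77, camera adjusted p = 1.84e-05, adjusted p = 0.283 with an estimated correlation). General stress genes rose in all 18 cases (median 1.34, camera adjusted p = 1.04e-07, adjusted p = 0.282 with an estimated correlation). GAD1 changed by 2.03 ± 0.07 and HSP12 by 0.90 ± 0.05. Sulfur assimilation genes rose in 19 of 20 cases and the other was not called (median 1.69, camera adjusted p = 1.69e-06, adjusted p = 0.39 with an estimated correlation). MET2 changed by 2.85 ± 0.13 and SUL1 by 2.82 ± 0.14. Genes of respiration rose in 38 of 42 cases and fell in 2 (median 0.66, camera adjusted p = 1.3e-07, adjusted p = 0.282 with an estimated correlation). Oxidative stress genes rose in 21 of 28 and fell in 3 (median 0.62, camera adjusted p = 0.00023, adjusted p = 0.282 with an estimated correlation). Proteasome genes rose in 32 of 33 and the other was not called (median 0.36, camera adjusted p = 9.13e-06, adjusted p = 0.39 with an estimated correlation). RPN4, which encodes their activator, changed by 0.98 ± 0.07.

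Ribosomal protein genes fell in 126 of 127 cases from WT(hsf1) to hac1∆(hsf1) and rose in 1 (median −1.76, camera adjusted p = 1.76e-34, adjusted p = 0.282 with an estimated correlation). RPS9A changed by −2.97 ± 0.09 (limma adjusted p = 3.22e-11). Ribosome biogenesis genes fell in 43 of 45 cases and rose in 1 (median −1.06, camera adjusted p = 8.57e-13, adjusted p = 0.282 with an estimated correlation). NSR1 changed by −2.41 ± 0.08. Among secretory genes 12 of 17 fell in ER folding and 1 rose (median −0.51, camera adjusted p = 0.00175, adjusted p = 0.436 with an estimated correlation). In translocation 11 of 13 fell and the rest were not called (median −0.69, camera adjusted p = 0.000312, adjusted p = 0.319 with an estimated correlation). In glycosylation 21 of 23 fell and 1 rose (median −0.61, camera adjusted p = 9.62e-06, adjusted p = 0.282 with an estimated correlation). In ER-Golgi transport 19 of 28 fell and 3 rose (median −0.34, camera adjusted p = 0.00293, adjusted p = 0.334 with an estimated correlation). MPD1 and EUG1, both of the disulfide isomerase family, changed by −2.17 ± 0.09 and −1.77 ± 0.10, and SIL1 by −1.56 ± 0.09. KAR2 was 1.22-fold lower (−0.29 ± 0.06, adjusted p = 0.000888) and PDI1 changed by −0.32 ± 0.06. ERO1 had −0.27 ± 0.12 (adjusted p = 0.0545) and IRE1 −0.11 ± 0.05 (adjusted p = 0.0516), neither of them called. Ergosterol synthesis genes fell in 16 of 23 cases and rose in 2 (median −0.44, camera adjusted p = 0.00141, adjusted p = 0.282 with an estimated correlation). ERG4, a sterol reductase, changed by −1.28 ± 0.07.

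Under the naming rule the largest increases were in TKL2, which rose 8.01-fold, SIP18 (2.98), PIR3, a cell wall protein (2.96), GRE1 (2.88), NQM1, a transaldolase (2.87), MET2, SSA3 (2.83) and SUL1. The largest decreases were in HAC1, RPS9A, SHM2, serine hydroxymethyltransferase (−2.78), RPL22B (−2.69), FET3 (−2.61), RPS22B (−2.60), RPS22A (−2.59) and RPS26B (−2.53), and URA3 changed by −1.31. There were 2274 genes higher and 1949 lower (limma), of which 351 and 415 by at least 2-fold. The arrays did not overlap for 4329 genes, against 10% by chance. Adjusted over the list alone, counts of passing lists were equal to those over all genes except for oxidative stress, with 4 lower. ERO1 was called without WT replicate 2 or 3 or hac1∆(hsf1) replicate 1, at −0.39 to −0.27. It was also called with the replicate number as a block in all strains, with median centring and with only genes above background, at −0.31 to −0.27. The same held with array weights and in a fit of the compared strains alone, at −0.31 and −0.27. IRE1 was called without WT replicate 2 or 3 or hac1∆(hsf1) replicate 2, at −0.15 to −0.11, and with quantile normalization, median centring or array weights, at −0.15 to −0.10. Cell wall genes did not pass (camera adjusted p = 0.0591, median 0.31) but did without WT replicate 2 or hac1∆(hsf1) replicate 3, at 0.31 and 0.32. Mating type and ploidy markers did not pass (camera adjusted p = 0.0688, median −0.31) but did without WT(hsf1) replicate 1, at −0.37. Median, mean and test differed in sign for auxotrophic markers (0.27, 0.18, down, camera adjusted p = 0.992), ER-associated degradation (−0.01, 0.01, up, camera adjusted p = 0.869) and mitochondrial chaperones (−0.13, 0.03, up, camera adjusted p = 0.953), none of which passed.

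hac1∆(hsf1) was last set against WT, to see which differences from WT the strain with both changes showed. Lists of ER folding, translocation, glycosylation and ER-Golgi transport were lower and cytosolic chaperones, as a list, higher than in WT. ER folding genes fell in 13 of 17 cases and the rest were not called (median −0.84, camera adjusted p = 1.51e-06, adjusted p = 0.282 with an estimated correlation). MPD1 changed by −2.53 ± 0.09 and SIL1 by −2.36 ± 0.09. KAR2 was 1.47-fold lower (−0.56 ± 0.06, limma adjusted p = 1.74e-05), ERO1 1.79-fold lower (−0.84 ± 0.12, adjusted p = 9.37e-05) and PDI1 changed by −0.48 ± 0.06. Translocation genes fell in 11 of 13 cases and the rest were not called (median −0.66, camera adjusted p = 3.07e-06, adjusted p = 0.282 with an estimated correlation). Glycosylation genes fell in 18 of 23 and rose in 1 (median −0.41, camera adjusted p = 1.34e-06, adjusted p = 0.282 with an estimated correlation). ER-Golgi transport genes fell in 20 of 28 and rose in 3 (median −0.36, camera adjusted p = 6.58e-06, adjusted p = 0.282 with an estimated correlation). HSF1 was 4.21-fold higher (2.07 ± 0.30, adjusted p = 9.82e-05) and SSA4 1.72-fold higher (0.78 ± 0.10, adjusted p = 5.56e-05). The WT mean of HSF1 includes WT replicate 2, at 9.61 against 8.08 and 8.11. The difference of HSF1 from the other WT arrays was therefore larger. In the list 16 of 21 cytosolic chaperone genes rose and 1 fell (median 0.23, camera adjusted p = 0.000597, adjusted p = 0.341 with an estimated correlation). SSA1 (0.05), HSP104 (−0.03), HSP12 (0.01) and IRE1 (0.02) were not called. Leaving out WT replicate 2 gave medians of −0.98 for ER folding, −0.73 for translocation and 0.26 for cytosolic chaperones, and these lists still passed.

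Ribosomal protein genes fell from WT to hac1∆(hsf1) in 121 of 127 cases and rose in 1 (median −0.53, camera adjusted p = 7.71e-27, adjusted p = 0.303 with an estimated correlation). Ribosome biogenesis genes fell in 31 of 45 and rose in 2 (median −0.32, camera adjusted p = 6.58e-06, adjusted p = 0.437 with an estimated correlation). Genes of respiration fell in 32 of 42 cases and rose in 2 (median −0.30, camera adjusted p = 5.12e-07, adjusted p = 0.282 with an estimated correlation). Ergosterol synthesis genes fell in 14 of 23 and rose in 3 (median −0.26, camera adjusted p = 0.0022, adjusted p = 0.282 with an estimated correlation). Cell wall genes rose in 12 of 20 cases and fell in 2 (median 0.20, camera adjusted p = 0.00175, adjusted p = 0.331 with an estimated correlation). PIR1, a cell wall glycoprotein, changed by 1.14 ± 0.14. Proteasome genes rose in 18 of 33 and the rest were not called (median 0.16, camera adjusted p = 0.000841, adjusted p = 0.502 with an estimated correlation). Mating type and ploidy markers fell in 10 of 16 cases and rose in 2 (median −0.41, camera adjusted p = 0.00395, adjusted p = 0.331 with an estimated correlation). The members that fell included the alpha-factor precursor gene MF(ALPHA)1 (−2.57 ± 0.16), expressed in alpha cells, and STE2 (−0.57 ± 0.06) and BAR1 (−0.83 ± 0.06), expressed in a cells. Glycolysis and fermentation genes fell in 9 of 18 cases and the rest were not called (median −0.12, camera adjusted p = 0.0443, adjusted p = 0.467 with an estimated correlation). That call ended without WT replicate 1 or 2 or hac1∆(hsf1) replicate 3, at −0.15 to −0.09, with quantile normalization, at −0.07, and with only genes above background.

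URA3 was 4.56-fold lower in hac1∆(hsf1) than in WT (−2.19 ± 0.07, limma adjusted p = 4.35e-10), and the other largest decreases under the naming rule were in HAC1, ULI1 (−4.19), MF(ALPHA)1, MPD1, SIL1, CYB5 (−2.29) and MCD4 (−2.21). The largest increases were in YOR338W (2.55, and 3.33 without WT replicate 2), SPO1 (2.14), SIP4 (2.10), HSF1, FLO8, a regulator of flocculation (2.07), SUC2 (1.99), ECM16 (1.98) and TRS65 (1.89). Over all genes 1581 were higher and 1530 lower (limma), of which 81 and 64 by at least 2-fold. Without WT replicate 2 the numbers at least 2-fold apart were 115 higher and 80 lower. The arrays did not overlap for 3146 genes, against 10% by chance. Adjusted over the list alone, counts of passing lists were equal except for ER folding (1 higher), ergosterol synthesis (15 lower), the cell wall (13 higher), respiration (3 higher and 34 lower), ribosomal proteins (122 lower) and ribosome biogenesis (32 lower). ER-associated degradation (camera adjusted p = 0.0532, median −0.11) passed without WT replicate 1 or 3, WT(hsf1) replicate 2 or hac1∆(hsf1) replicate 2, at −0.13 to −0.10, and the iron regulon (camera adjusted p = 0.121, median 0.19) passed without hac1∆(hsf1) replicate 1, at 0.29. HSP82 changed by 0.10 ± 0.04 (adjusted p = 0.0483), a call that ended on leaving out any array except hac1∆(hsf1) replicate 1, at 0.08 to 0.11. It also ended with quantile normalization or median centring, at 0.07, and with only genes above background, with an intensity trend, with array weights and in a fit of the compared strains alone, at 0.10.

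The interaction tests whether the hsf1 effect differed between cells without and with HAC1, and it was positive where the effect was more positive without HAC1. At camera's preset correlation it was positive for the lists of cytosolic chaperones, general and oxidative stress, the proteasome, respiration and sulfur assimilation. It was negative for those of ribosomal proteins, ribosome biogenesis, glycosylation and ergosterol synthesis, and no list passed with an estimated correlation. The interaction was 2.92 ± 0.42 for HSF1 (limma adjusted p = 4.13e-05), 3.43 ± 0.15 for SSA4 (adjusted p = 8.05e-10), 1.02 ± 0.08 for HSP104, 0.85 ± 0.06 for HSP82 and 0.68 ± 0.09 for SSA1. The interaction of HSF1 was smaller without WT replicate 2, where HSF1 changed by 0.43 instead of −0.08 from WT to WT(hsf1). For the ER genes it was 1.81 ± 0.17 for ERO1 (adjusted p = 8.22e-07) and 1.31 ± 0.09 for KAR2 (adjusted p = 3.78e-08), both of which fell in WT(hsf1) and rose in hac1∆(hsf1). It was −0.29 ± 0.07 for IRE1 (adjusted p = 0.00203). HAC1 had −0.20 ± 0.12 (adjusted p = 0.161) and PDI1 −0.04 ± 0.08 (adjusted p = 0.669), neither of them called. Since HAC1 was below background in both hac1∆ strains, its interaction mostly repeats its change from WT to WT(hsf1) with the sign turned, as does its call at −0.31 without WT replicate 1. URA3 had −1.65 ± 0.09 (adjusted p = 8.77e-09) and HSP12 1.26 ± 0.07 (adjusted p = 1.13e-08).

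By list, the interaction was positive for 19 of 21 cytosolic chaperones and negative for 1 (median 1.02, camera adjusted p = 1.51e-06, adjusted p = 0.282 with an estimated correlation). It was positive for all 18 general stress genes (median 1.76, camera adjusted p = 2.41e-09, adjusted p = 0.282 with an estimated correlation). Among sulfur assimilation genes it was positive for 16 of 20 and negative for 2 (median 1.33, camera adjusted p = 0.00021, adjusted p = 0.498 with an estimated correlation), and among oxidative stress genes positive for 20 of 28 and negative for 4 (median 0.76, camera adjusted p = 0.000113, adjusted p = 0.282 with an estimated correlation). For respiration genes it was positive in 35 of 42 cases and negative in 2 (median 0.68, camera adjusted p = 1.04e-07, adjusted p = 0.282 with an estimated correlation), and for proteasome genes positive in 19 of 33 and the rest not called (median 0.22, camera adjusted p = 0.0138, adjusted p = 0.595 with an estimated correlation). Negative values held for 126 of 127 ribosomal protein genes, and the other was not called (median −2.01, camera adjusted p = 1.74e-36, adjusted p = 0.282 with an estimated correlation). Among ribosome biogenesis genes 42 of 45 were negative and 1 positive (median −1.19, camera adjusted p = 8.31e-13, adjusted p = 0.282 with an estimated correlation). Among ergosterol genes 21 of 23 were negative and 2 positive (median −0.61, camera adjusted p = 2.06e-05, adjusted p = 0.282 with an estimated correlation). Among glycosylation genes 16 of 23 were negative and 2 positive (median −0.47, camera adjusted p = 0.00255, adjusted p = 0.375 with an estimated correlation). Adjusted over the list alone, counts of passing lists were equal to those over all genes except for the proteasome (18 positive) and glycosylation (18 negative).

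Under the naming rule the most positive interactions were in SIP18 (5.05), SHH3 (4.81), GRE1 (4.58), SUL1 (4.54), SSA3 (4.35), SPG4, a stationary phase gene (4.28), TKL2 (4.23) and HEF3, a translation elongation factor (4.21). The most negative were in RPS9A (−3.15), RPS22B (−3.06), RPL17B (−3.03), RPL22B (−2.97), ASC1, a protein of the small ribosomal subunit (−2.94), RPS8B (−2.85), RPS24B (−2.77) and RPL6B (−2.76). There were 1945 genes with a positive and 1850 with a negative interaction (limma), of which 446 and 470 by at least 2-fold. ER-associated degradation did not pass (camera adjusted p = 0.0885, median 0.22) but did without WT replicate 2, at 0.21. Median, mean and test differed in sign for amino acid synthesis (−0.19, 0.01, down, camera adjusted p = 0.324), auxotrophic markers (0.26, 0.09, down, camera adjusted p = 0.922) and the cell wall (−0.03, 0.03, down, camera adjusted p = 0.76), none of which passed. Neither amino acid synthesis nor auxotrophic markers passed in any of the 6 comparisons.

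**Figure D3:**
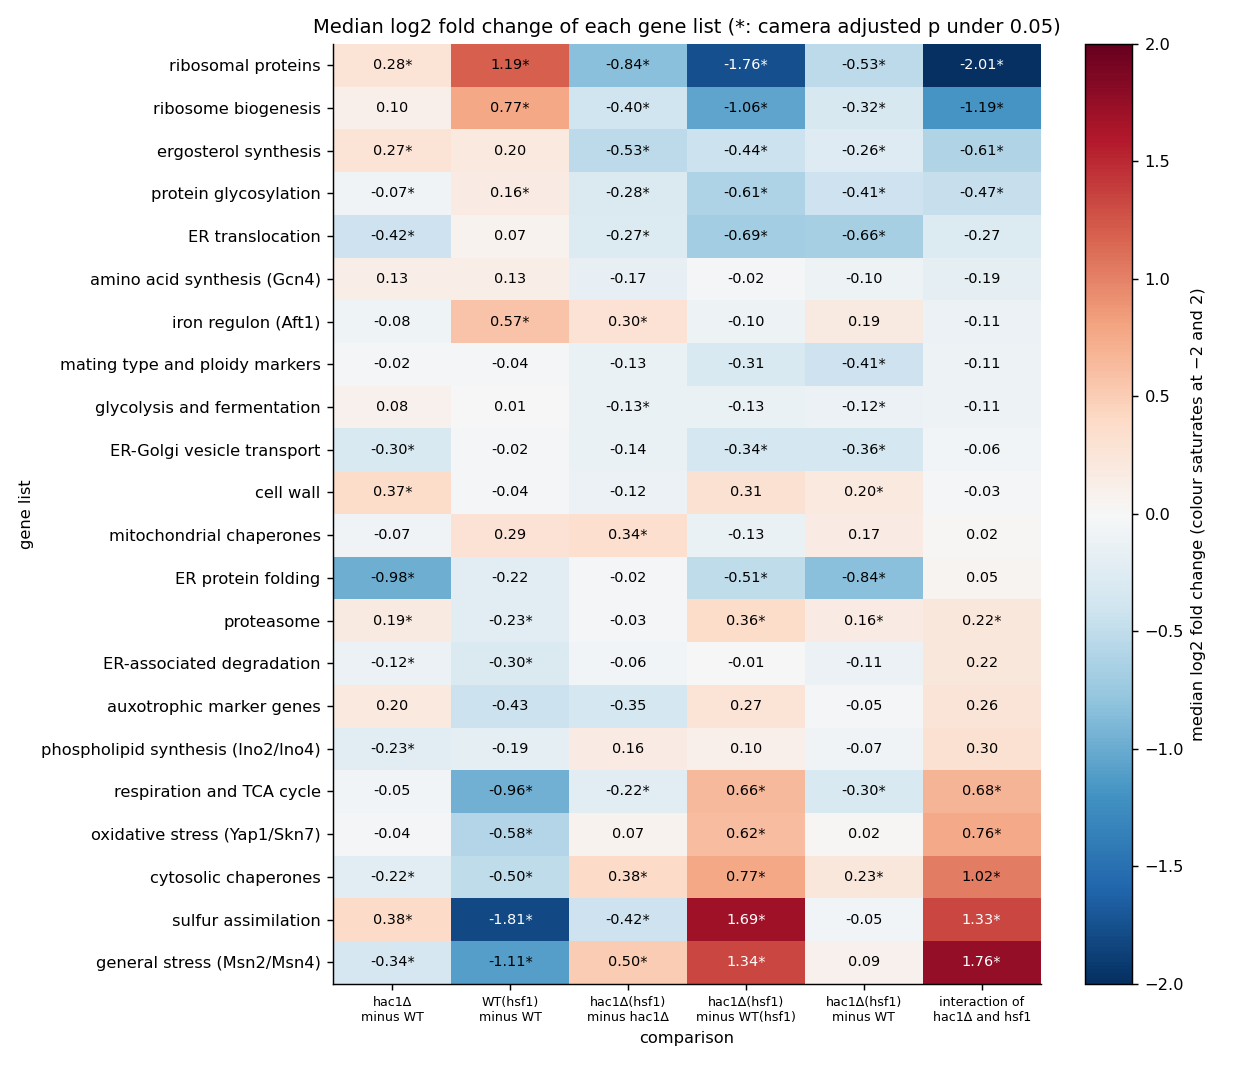
Median log2 fold change of the 22 gene lists (vertical axis) in the 6 comparisons (horizontal axis), with the value in each cell and an asterisk where the camera adjusted p was under 0.05 at the preset correlation. Ribosomal proteins run from 1.19 in WT(hsf1) minus WT to −2.01 in the interaction, and general stress genes from −1.11 to 1.76.

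Across the 5449 genes the hsf1 effect in WT cells and that in hac1∆ cells, which share no array, had a Pearson correlation of −0.44 and a Spearman correlation of −0.48, and genes are not independent replicates. Leaving out WT replicate 2 gave −0.37 and −0.41. Of the called genes 186 were higher in both pairs of strains, where independent calls would give 465.8, and 248 were lower in both, against 564.9. Genes higher with hsf1 in WT cells and lower in hac1∆ cells numbered 1009, against 540.4. Genes lower in WT cells and higher in hac1∆ cells numbered 853, against 486.9. The effect of losing HAC1, measured without and with the addition, had a correlation across genes of −0.08, and of 0.03 without WT replicate 2.

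**Figure D4:**
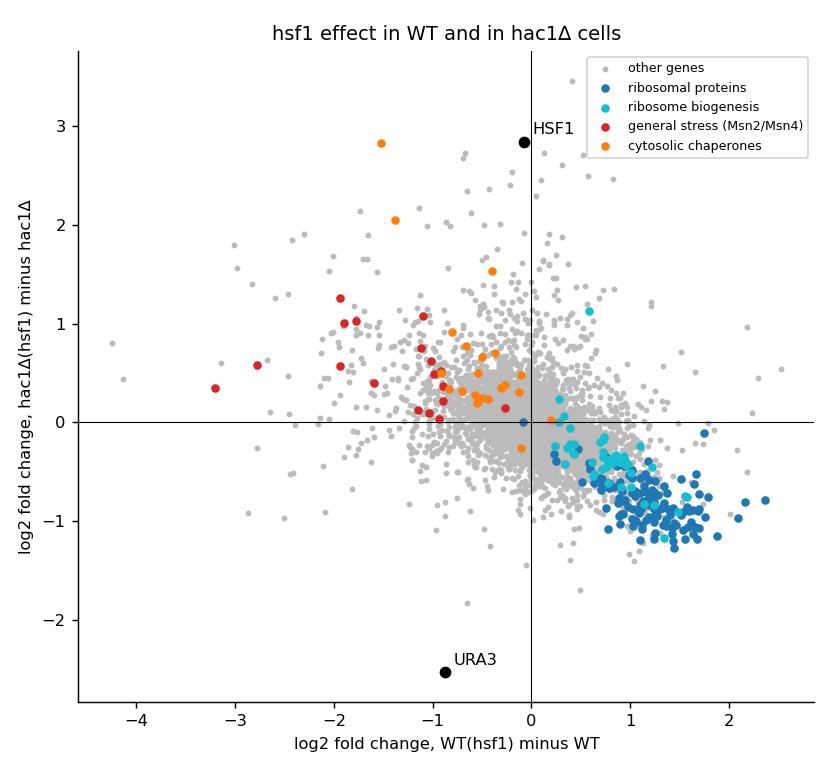
Log2 fold change of each of the 5449 genes in WT(hsf1) minus WT (horizontal axis) and in hac1∆(hsf1) minus hac1∆ (vertical axis), with 4 gene lists coloured and HSF1 and URA3 in black. Ribosomal protein genes (medians 1.19 and −0.84) lie at the lower right and general stress genes (−1.11 and 0.50) at the upper left, and the correlation across genes is −0.44.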

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

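The tests of explanations in this part, the other splits of the arrays included, were chosen only after the results were seen, while the interaction itself was planned.

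A difference between groups marked the hsf1 effect, which the interaction compared between hac1∆ and WT cells. By limma, 1945 genes had a more positive and 1850 a more negative hsf1 effect in hac1∆ than in WT cells. The more positive effects were in the heat shock factor gene HSF1 (2.92, smaller without WT replicate 2) and its known chaperone targets SSA4 (3.43), HSP104 (1.02), HSP82 (0.85) and SSA1 (0.68). They were also seen in the ER genes ERO1 (1.81) and KAR2 (1.31) and in the stress gene HSP12 (1.26). IRE1 (−0.29) and URA3 (−1.65) had a more negative effect. The largest positive values belonged to SIP18 (5.05), SHH3 (4.81), GRE1 (4.58), SUL1 (4.54), SSA3 (4.35), SPG4 (4.28), TKL2 (4.23) and HEF3 (4.21). The largest negative values belonged to RPS9A (−3.15), RPS22B (−3.06), RPL17B (−3.03), RPL22B (−2.97), ASC1 (−2.94), RPS8B (−2.85), RPS24B (−2.77) and RPL6B (−2.76).

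Among gene lists the median interaction was 1.76 for general stress, 1.33 for sulfur assimilation, 1.02 for cytosolic chaperones, 0.76 for oxidative stress, 0.68 for respiration and 0.22 for the proteasome. It was −2.01 for ribosomal proteins, −1.19 for ribosome biogenesis, −0.61 for ergosterol synthesis and −0.47 for glycosylation. These lists passed camera with its preset correlation and none of them with an estimated one, where the smallest adjusted p over all lists was 0.282.

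The hsf1 effects in WT and hac1∆ cells tended to have opposite signs across genes, with a correlation of −0.44. Not all genes did so, since 186 were called higher in both pairs and 248 lower in both. List medians were negative in both for sulfur assimilation (−1.81 and −0.42) and respiration (−0.96 and −0.22), and positive in both for the iron regulon (0.57 and 0.30). WT replicate 2 as the whole cause of the negative correlation is argued against, since the correlation without it was −0.37. Exchanged labels in one pair of strains would turn HSF1 and URA3 in that pair, but without WT replicate 2 HSF1 was higher in both pairs (0.43 and 2.84) and URA3 lower in both (−0.96 and −2.53); it stays open because HSF1 had −0.08 with all arrays and the labels do not say what hsf1 is. Another growth state of the cultures of 1 strain could also give it, and the correlation of −0.41 over the 4865 genes outside the lists cannot tell this apart, since growth changes such genes too. By the interaction the hsf1 effect differed between these strains, but that HAC1 itself is the reason stays open as an untested biological hypothesis. The labels also do not say that the addition was equal in both strains. HSF1 rose unequally, by 0.43 in WT cells without WT replicate 2 and by 2.84 in hac1∆ cells. Whether this gave the opposite signs was not tested.

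For the comparisons of 3 arrays with 3 there are 10 splits of the arrays, too few for a share under 0.05. In each of them 1 of 10 splits, the real one, called as many genes by limma. The real split called 2764 genes for hac1∆ minus WT, 3600 for WT(hsf1) minus WT, 3115 for hac1∆(hsf1) minus hac1∆, 4223 for hac1∆(hsf1) minus WT(hsf1) and 3111 for hac1∆(hsf1) minus WT. The highest of the other splits called 0 in all 5, and at an unadjusted p under 0.05 it called 371, 197, 624, 164 and 1207. For the interaction 1 of 100 splits, the real one, called as many as its 3795 genes, and the highest other called 2269. The other splits mix arrays of different strains, whose differences then add to the spread within groups. The count therefore cannot tell a difference in the hsf1 effect from other differences between strains, and no conclusion on the interaction is drawn from it.

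Outside the genes compared, 356 probe sets with no listed gene had a mean above background, and they were not analysed here.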

How the results depend on the processing

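The omission of WT replicate 2 from the counts at least 2-fold apart, the alternatives for shared calls and the block in the hac1∆ strains alone were chosen after the data were seen, and the other tests here were planned. Over the alternatives other than a 2-fold minimum and an estimated correlation, and over the 12 fits that each left out 1 array, the counts of genes higher and lower stayed within 1.5 times their value. Over all alternatives run, the calls of the named genes kept their direction and side of the threshold in 8738 values, were lost in 54, gained in 15, moved in 12 and turned in 2. For the lists 2677 values kept both, 79 lost the call (72 of them with an estimated correlation), 13 gained it and 25 moved. Both turned values belong to HSF1 in WT(hsf1) minus WT, which was −0.08, and 0.37 with array weights. Leaving out 1 array gave −0.34 to 0.43, the highest without WT replicate 2, whose own HSF1 level of 9.61 lay above 8.08 and 8.11. With an estimated correlation camera passed 0 lists against 72, with 14 at an unadjusted p under 0.05, and fry passed 113. Leaving out 1 array gave 72 to 74 at the preset correlation. Correlation between genes alone does not account for the loss of calls. For mitochondrial chaperones in hac1∆(hsf1) minus hac1∆ the estimate was −0.000109, below the preset 0.01. Their unadjusted camera p still rose from 0.00419 to 0.0184.

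A 2-fold minimum, which by its construction removes smaller changes, left 12 genes higher and 89 lower for hac1∆ minus WT, 195 and 215 for WT(hsf1) minus WT, 141 and 50 for hac1∆(hsf1) minus hac1∆, 351 and 415 for hac1∆(hsf1) minus WT(hsf1), 81 and 64 for hac1∆(hsf1) minus WT, and 446 and 470 for the interaction. Of these, without WT replicate 2 the 12 became 20 and the 81 and 64 became 115 and 80, and the cause was not tested. Genes higher with hsf1 in both WT and hac1∆ cells numbered 186, and 310 with array weights, which gave WT replicate 2 the lowest weight, 0.244, and the cause was not tested. The correlation of the hsf1 effects ran from −0.48 to −0.37 on leaving out 1 array. No scaling moved the median of all genes by more than 0.1.

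The labels number the replicates 1 to 3 but do not say that equal numbers belong together. Of 18 pairs of arrays with equal numbers, 8 had a residual correlation over 0.1 (−0.25 to 0.50), and 5 of 12 arrays were closest to one of their own number. Pairs with unequal numbers were not counted, so these counts alone do not show that equal numbers belong together. Among the pairs of strains, only hac1∆ and hac1∆(hsf1) had all their correlations over 0.1. With the replicate number as a block in all strains, genes higher and lower numbered 1585 and 1259 for hac1∆ minus WT, 1769 and 1871 for WT(hsf1) minus WT, 1467 and 1705 for hac1∆(hsf1) minus hac1∆, 2281 and 1966 for hac1∆(hsf1) minus WT(hsf1), 1639 and 1545 for hac1∆(hsf1) minus WT, and 1978 and 1876 for the interaction. This block added a call of ERO1 in hac1∆(hsf1) minus WT(hsf1), at −0.27, and changed no other call of a named gene or list. With the block in the hac1∆ strains alone, 1484 genes were higher and 1727 lower for hac1∆(hsf1) minus hac1∆, against 1442 and 1673, and no call of a named gene or list changed. The alternatives for linear values, with a pseudocount, were not run because the values are logarithms. Signals near the floor limit what can be seen, since 213 of 5449 genes had a mean at or below the background of 5.49. In simulated data, changes of 0.25, 0.5 and 1 on the log2 scale were recovered in 57.4, 93.9 and 100% of genes for hac1∆ minus WT and in 25, 74.2 and 100% for the interaction. There 5249 of 5449 genes were left unshifted and the noise was independent between genes. Far more genes were called in the real data, so these shares are not the sensitivity of the reported fits.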

Other observations

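The genes and tests in this part were chosen only after the results were seen. The single genes named first were not tested as groups. With hsf1, the uracil synthesis genes URA2 and URA4 changed by −1.41 ± 0.09 and −0.84 ± 0.04 in hac1∆ cells and by 1.04 ± 0.09 and 0.49 ± 0.04 in WT cells. URA1 and URA5, later in the pathway, changed by −1.70 ± 0.07 and −0.69 ± 0.05 in hac1∆ cells and by 0.49 ± 0.07 and 0.89 ± 0.05 in WT cells. FUI1, the uridine permease, changed by −1.33 ± 0.09 in hac1∆ cells and by 0.98 ± 0.09 in WT cells. URA10, a minor isozyme of URA5, went the other way, with 1.02 ± 0.08 and −1.17 ± 0.08. URA3 fell in both, with −2.53 and −0.88.

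From WT(hsf1) to hac1∆(hsf1) the glycine decarboxylase genes GCV1 and GCV2 changed by −2.51 ± 0.06 and −1.48 ± 0.07, MTD1, a folate dehydrogenase, by −1.66 ± 0.06, and the purine genes ADE17 and ADE13 by −2.52 ± 0.10 and −1.85 ± 0.07. From WT to hac1∆ they changed by −1.03 ± 0.06, −0.73 ± 0.07, −0.29 ± 0.06, −0.53 ± 0.10 and 0.49 ± 0.07 in the same order. From WT to WT(hsf1) all 5 rose, with 1.33 ± 0.07 for GCV2, 1.44 ± 0.10 for ADE17 and 1.53 ± 0.07 for ADE13. HXT7, a high-affinity glucose transporter, changed by −1.90 ± 0.10 in hac1∆ minus WT, −1.05 ± 0.10 in WT(hsf1) minus WT and 1.99 ± 0.10 in hac1∆(hsf1) minus hac1∆. HSP30, a stress protein of the plasma membrane, changed by −1.32 ± 0.14, −1.74 ± 0.14 and 2.14 ± 0.14 in the same comparisons. PDR5, a drug efflux pump, changed by 2.08 ± 0.07 in WT(hsf1) minus WT and −1.76 ± 0.07 in hac1∆(hsf1) minus WT(hsf1).

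AGX1, the gene next to HAC1 in assembly R64, was higher without HAC1 in both backgrounds, by 0.86 ± 0.12 in hac1∆ minus WT and 2.69 ± 0.12 in hac1∆(hsf1) minus WT(hsf1). By the smaller of these changes it ranked 9 among the 5449 genes. With hsf1, AGX1 changed by −1.67 ± 0.12 in WT cells (limma adjusted p = 8.17e-08). In hac1∆ cells it changed by 0.16 ± 0.12 (limma adjusted p = 0.294, and 0.0207 without WT replicate 2). The 2.69 therefore includes the lower level of AGX1 in WT(hsf1). RIM15, the neighbour on the other side, had 0.03 ± 0.07 (limma adjusted p = 0.743) and 0.96 ± 0.07 (adjusted p = 8.68e-08).

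WT replicate 2 differed from the other WT arrays, and for 195 of 195 genes at least 2-fold apart between hac1∆(hsf1) and those arrays it lay between their levels. Material from WT(hsf1) or hac1∆ is argued against, since genes that set these strains apart but not hac1∆(hsf1) moved toward them by a median linear share of at most 0.0124. Material from hac1∆(hsf1) in that sample may account for the difference: the median linear share was 0.363 over the 195 genes (quartiles 0.297 and 0.412), 0.384 for the 115 higher and 0.297 for the 80 lower in hac1∆(hsf1), where WT replicates 1 and 3 set against each other gave 0.0032 and 0.0155. The shares of single genes were 0.375 for HSF1, 0.205 for HAC1 and 0.198 for URA3, where a mixture alone predicts equal shares. HAC1 and URA3 belong to the 23 genes lower in hac1∆(hsf1) with a WT level over 10, whose median share was 0.276. Another state of that culture stays open, because one that moved every gene toward hac1∆(hsf1) in proportion would also leave the SD of 0.0789 over genes that was left after the share, against 0.102 between the other WT arrays.

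The 140 genes other than HSF1 at least 2-fold higher in hac1∆(hsf1) than in hac1∆, where HSF1 was 7.18-fold higher, might follow the level of the HSF1 transcript. Without WT replicate 2, where HSF1 was 0.43 higher in WT(hsf1) than in WT, 49 of them were higher in WT(hsf1), 63 lower and 28 not called, with a median of −0.07. The share higher was 35% against 32% of all genes (Fisher's exact test, two-sided p = 0.463). With all 12 arrays, where HSF1 changed by −0.08, 18 were higher, 65 lower and 57 not called, with a median of −0.28, and the share higher was 12.9% against 32.3% of all genes (Fisher's exact test, p = 1.14e-07). Both p-values treat genes as independent, which they are not. WT replicate 2 also lay toward hac1∆(hsf1), the strain in which these genes were high, so with all arrays the test measures that array too. These counts leave the hypothesis open, because the rise of HSF1 in WT cells was small and the count rests on WT replicate 2.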
